A study of Caenorhabditis elegans with 2 samples.

How the data were processed

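Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole young adult hermaphrodites of a transgenic strain with LSY-27 tagged by GFP and FLAG. There were 2 biological replicates, numbered 2 and 3 in the labels, in a single group. The files were lists of regions in narrowPeak format, deposited for builds ce10 and ce11. Per the deposited text beside the lists, a relaxed list of regions and background was called for each replicate against a control, a further relaxed list was called on the pooled replicates, and a thresholded list was made by the irreproducible discovery rate (IDR) method from both replicates' lists and the pooled list. The peak caller, the IDR settings, the aligner and the read depths were not given in the sources used here, so the treatment of reads that match several places is unknown and no interval based on reads could be computed. The control was not analysed here.

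The signal value of each region, in column 7 of the deposited lists, is the authors' own score, and its scaling was not given in the sources used here. It was used to rank, filter and describe regions within a list, and between the replicates' lists only in correlations, which need no common scale. The deposited column 9 holds −log10 q-values, which were the same, 3.47, for every thresholded region and were not used to rank them. Column 10 holds the position of the summit, and the p-value column held a placeholder throughout. The pooled relaxed list held exactly 30000 regions, and the relaxed lists held 12414 regions for replicate 2 and 29326 for replicate 3. The overlap of the replicates was tested on equal numbers of their strongest regions, while thresholded regions were matched to the full relaxed lists, whose lengths differ.

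The ce11 lists were set against the reference genome and RefSeq annotation of the same assembly (WBcel235), and every region of the ce11 lists ended within its chromosome. The annotation gave 19983 protein-coding genes. A summit was assigned to a protein-coding gene when it lay from 1000 bp upstream to 200 bp downstream of the annotated 5′ end. A summit was counted as near a non-coding gene when it lay within 500 bp of the gene. Mitochondrial genes are transcribed together, so their 5′ ends are not separate promoters. Regions were counted as shared when they overlapped by at least 1 bp.

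The tests of the main comparisons were chosen before the data were examined. Shares of summits were compared with 10000 random placements of the same number of summits on each chromosome, with a two-sided permutation p of at least 0.0002. Counts per chromosome were compared with length, and counts in the central 50% of the autosomes (25 to 75% of the length) with an even split, by exact binomial tests. The 27 gene lists, covering ASE asymmetry genes, housekeeping classes, tissues and gene families, were tested with two-sided Fisher's exact tests against all protein-coding genes. For each 6-mer, counted as 1 item with its reverse complement, windows of 50 bp on each side of the summit were compared with windows centred 300 bp to the left or right by an exact McNemar test. Replicates were compared by the overlap of equal numbers of strongest regions against 10000 circular shifts, and by correlations with 100000 permuted pairings. Differences of medians used 100000 permutations. Adjusted p-values follow Benjamini and Hochberg within each family, with a threshold of 0.05, and intervals of shares are exact Clopper-Pearson 95% intervals, which treat regions as independent and cover counting error only. The smallest p that resampling can give is 1e-05. With a single group, p-values describe regions of these lists and not differences between samples.

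The rule for named items was also fixed beforehand. It took the 20 regions with the highest signal found in both replicates, any region at lsy-27 or an ASE asymmetry gene, up to 4 genes of each list that passed and 2 of each other list, and the 5 most enriched and 2 most depleted 6-mers. Because all of the 20 strongest regions were mitochondrial, the 20 strongest nuclear regions were added after the values were seen, as were the SL2 genes, single tRNA isotypes, the nuclear-only settings and the split by distance to tRNA, snRNA and snoRNA genes. The tests between the sets of that split, of summit positions at tRNA against snoRNA genes, of signal by class and of isotypes were likewise chosen after the data were seen.

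Alternatives were a stricter signal threshold, the strongest 342 regions of each replicate alone, other windows and distances, other random models or backgrounds, other overlap rules, 8-mers and the ce10 lists. Analyses were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The tests were first run on simulated data. With 100 uniform sets of 300 summits, 6% passed the placement test for protein-coding 5′ ends and 2% that for tRNA genes. A planted share of 20.0% near tRNA genes was recovered as 20.7%, all 15 planted list members were recovered with no other list passing, a planted 6-mer ranked 1, and 102 regions were found shared where 100 had been planted.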

Results

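The data were lists of regions called from chromatin immunoprecipitation of LSY-27, a C2H2 zinc finger transcription factor of Caenorhabditis elegans that is required for the left/right asymmetry of the ASE taste neurons. The factor carried a C-terminal green fluorescent protein (GFP) and FLAG tag in a transgenic strain, and chromatin was immunoprecipitated from whole young adult hermaphrodites through GFP, according to the sample descriptions. The antibody label names lsy-27 itself, which differs from those descriptions. There was a single group with 2 biological replicates, numbered 2 and 3, and no contrasting stage, strain or factor, so every comparison below is between regions of the genome or between the replicates. The read depth of the libraries was not given in the sources used here, and the control used for peak calling was not analysed here. Coordinates are those of build ce11, counted from 1, and signal values are the authors' own score per region.

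The thresholded list held 342 regions with a median width of 316 bp, covering 0.106% of the genome. Of these, 318 lay on the nuclear chromosomes and 24 on mitochondrial DNA. The mitochondrial regions had the highest signal values, with a median of 158 against 27.1 for the nuclear regions. All 20 of the regions with the highest signal values found in both replicates were mitochondrial. The strongest spanned positions 4369 to 4931, with its summit in the coding sequence of CYTB (cytochrome b) and a signal of 1050, followed by 12256 to 12563 in ND5 (a subunit of NADH dehydrogenase) with 744. Because mitochondrial DNA has no nucleosomes and many copies per cell, the nuclear regions are also described separately, a choice made after the signal values were seen.

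Most of the strongest nuclear regions lay at short non-coding RNA genes. Among the 20 nuclear regions with the highest signal found in both replicates, 10 had a small nucleolar RNA (snoRNA) gene within 500 bp, 6 a transfer RNA (tRNA) gene and 1 a small nuclear RNA (snRNA) gene. The highest signal, 61.9, was on chromosome II at 5844659 to 5844974, between protein-coding genes and at −48 bp from the 5′ end of sls-2.1 (negative positions are upstream), which encodes a spliced leader RNA of the SL2 type. The next was on chromosome V at 11314081 to 11314396, in an intron of cutl-18, with a signal of 60.7 and its summit at −19 bp from the 5′ end of the snoRNA gene T03F7.8. On the X chromosome, the region from 3035914 to 3036229 had a signal of 57.9 and its summit lay between the tRNA genes M02F4.t2 (glutamate) and M02F4.t1 (glycine). Of the 3 regions with none of these genes nearby, the one on chromosome I at 13463820 to 13464135 lay in an intron of ints-8, with its summit 23 bp inside rpr-1, which encodes the RNA of ribonuclease P, and had a signal of 44.6. The remaining regions of the 3 lay in introns of mdt-26, a Mediator subunit gene, and gpa-1, a G protein alpha subunit gene, with signals of 50.1 and 42.5.

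Over the whole thresholded list, 136 of 342 summits (39.8%, exact Clopper-Pearson 95% interval 34.5 to 45.2) lay within 500 bp of a tRNA gene, 55 (16.1%) within that distance of a snoRNA gene and 13 (3.80%) of an snRNA gene. Random placement on the same chromosomes gave means of 18.3, 1.18 and 0.389 summits. Each of the 3 classes passed the test with an adjusted permutation p of 0.0004, the smallest that 10000 placements over 6 classes gave. Most of the random summits at tRNA genes fell on the small mitochondrial genome, and among nuclear regions the shares were 38.1% for tRNA (121 of 318, against a random mean of 1.98), 17.3% for snoRNA and 4.09% for snRNA genes. The other nuclear regions of the pooled relaxed list, which holds weaker regions and background, lay near tRNA genes in 1.42% of cases (exact Fisher adjusted p = 7.1e-128), near snoRNA genes in 0.763% and near snRNA genes in 0.287%. Ribosomal RNA genes (5 summits, all mitochondrial), microRNA genes (2 summits) and piwi-interacting RNA genes (14 summits, against a random mean of 15.8) did not pass the test. The microRNA genes were mir-5549 and mir-51, named after their values were seen. MicroRNA genes passed the test when the strongest regions of a single replicate were used, with 5 of 342 summits in replicate 2 and 4 of 342 in replicate 3 (adjusted permutation p = 0.006 and 0.029).

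**Figure D1:**
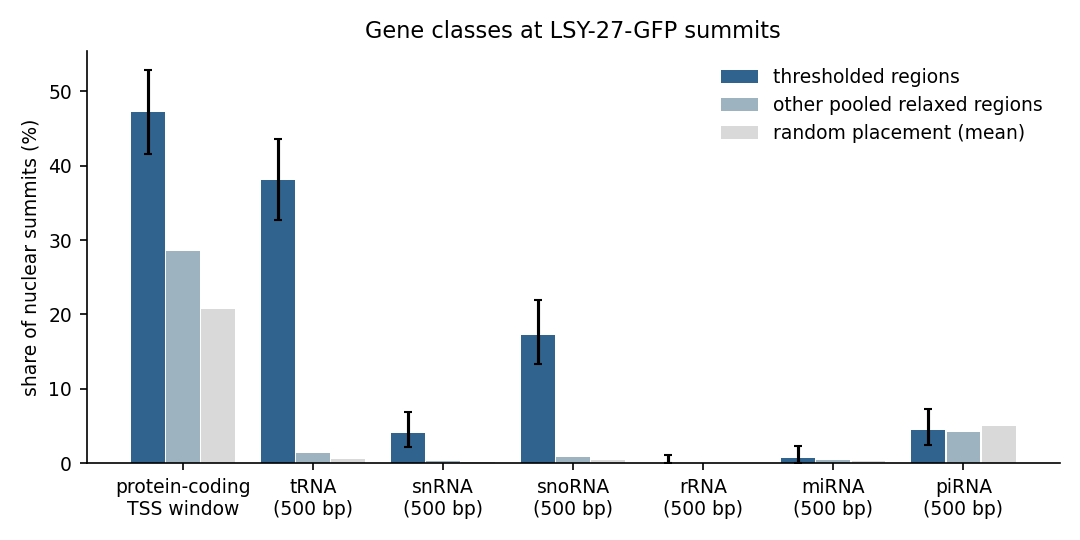
Share of nuclear summits (%) in the window of a protein-coding 5′ end (TSS window, 1000 bp upstream to 200 bp downstream) or within 500 bp of each non-coding class, for the 318 thresholded regions (dark bars, with exact 95% intervals), the other pooled relaxed regions and random placement. Thresholded summits lay near tRNA genes in 38.1% of cases, against 1.42% of the other regions.

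Counted by gene, 147 of the 612 nuclear tRNA genes (24.0%, exact 95% interval 20.7 to 27.6), 57 of the 346 snoRNA genes (16.5%) and 13 of the 129 snRNA genes (10.1%) had a nuclear thresholded summit within 500 bp. Genes for all 20 standard amino acids were represented, from 4 of 39 leucine tRNA genes (10.3%) to 12 of 27 glutamine tRNA genes (44.4%). A difference between isotypes did not pass the test (permutation p = 0.34, chi-square statistic 22.1 over 21 isotypes). At tRNA genes the median summit was 28 bp downstream of the 5′ end. At snoRNA genes the median summit was at −27 bp, and 41 of the 57 genes (71.9%) had the summit upstream. These medians differed by 55 bp (permutation p = 2e-05, two-sided). Neighbouring genes can share a summit, and the 147 tRNA genes had 121 summits near them. Tests and intervals by gene, including that of isotypes, treat genes as independent and do not allow for this sharing. The snRNA genes with summits included sls-2.1, sls-2.4, sls-2.8, sls-2.9 and sls-2.16 of the SL2 type. These genes were counted after the enrichment of their classes had been seen. Most tRNA genes have near-identical copies. Of the 26 tRNA genes with at least 90% of their 32-mers found once in the genome, only K02A4.t1 had a summit within 500 bp, a share of 3.85%, against 24.9% of the other tRNA genes (exact Fisher p = 0.0094). That summit was 359 bp from the 5′ end of K02A4.t1 and inside the neighbouring tRNA gene K02A4.t2, so none of the 26 had a summit within the gene itself.

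**Figure D2:**
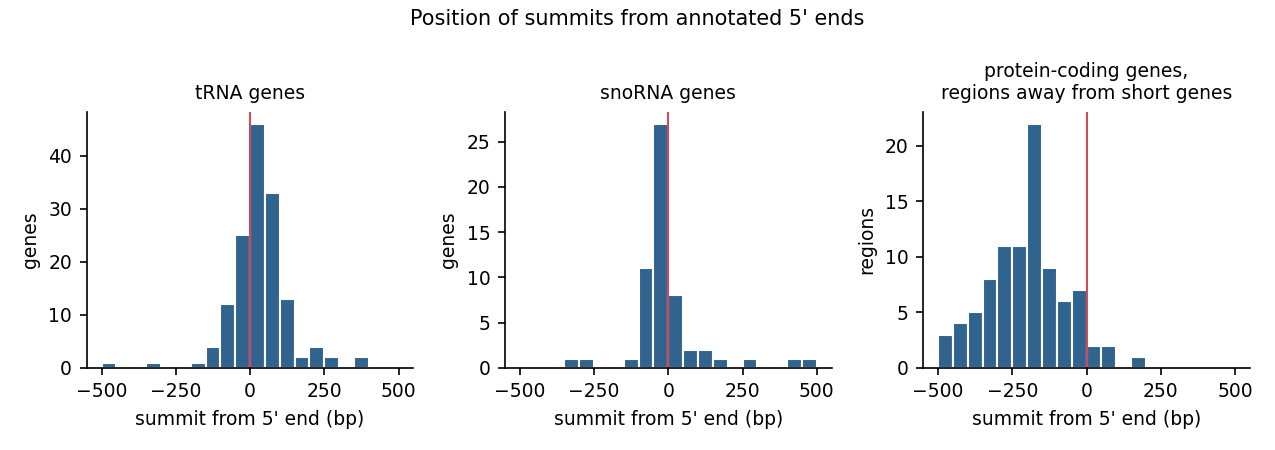
Distance in bp from the annotated 5′ end to the summit, in bins of 50 bp. Shown are 147 tRNA genes, 57 snoRNA genes and the 131 nuclear regions away from tRNA, snRNA and snoRNA genes. For those regions the nearest protein-coding 5′ end was used. Negative values are upstream, the red line marks the 5′ end, and distances beyond 500 bp are not drawn. Medians were 28 bp for tRNA genes and −27 bp for snoRNA genes.

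Protein-coding promoters formed the other large group. Of the 342 summits, 170 (49.7%) lay between 1000 bp upstream and 200 bp downstream of a protein-coding 5′ end, against a mean of 84.5 under random placement (permutation p = 0.0002, two-sided, the smallest that 10000 placements can give). Nuclear summits made up 150 of the 170, or 47.2% of 318, against a random mean of 66.0 (permutation p = 0.0002). The others of the 170 were mitochondrial, where 5′ ends are not separate promoters. The other regions of the pooled relaxed list lay in these windows in 28.5% of cases (exact Fisher p = 2.4e-16). The nuclear regions differed in this respect by their distance to tRNA, snRNA and snoRNA genes, called short genes below. This split was chosen after the data were seen, and regions at other small RNA genes, such as rpr-1, count as away from short genes. Of the 187 regions within 500 bp of a tRNA, snRNA or snoRNA gene, 44 (23.5%) were in such a window, against a random mean of 38.5 (permutation p = 0.36). Of the remaining 131 regions, 106 (80.9%) were, against 27.6 (permutation p = 0.0002). These shares differed (exact Fisher adjusted p = 5.7e-24 over 6 features compared between the sets). Those 131 summits had a median position of −194 bp from the nearest protein-coding 5′ end, and 113 of them lay between protein-coding genes. Signal values at protein-coding 5′ ends (median 27.7, n = 170) and elsewhere (median 27.3, n = 172) did not differ past the threshold (permutation p = 0.57, two-sided). With nuclear regions only the direction turned, with medians of 26.3 (n = 150) and 27.2 (n = 168), also not past the threshold (permutation p = 0.32). Nuclear regions near snoRNA genes had a higher median signal than the 131 regions away from short genes (32.1 against 25.5, adjusted permutation p = 0.00015), while those near tRNA genes had 27.1 (adjusted permutation p = 0.096).

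Among protein-coding genes, 3 of the 27 lists had thresholded summits at the 5′ end more often than other genes. Of the 75 genes for cytosolic ribosomal proteins, 18 (24.0%) had one, against 226 of 19983 protein-coding genes (1.13%; exact Fisher adjusted p = 6.8e-18 over 27 lists). Those with the highest signal were rpl-35 (41.2), rps-3A (35.7), rpl-18A (33.7) and rps-28 (33.3). Away from tRNA, snRNA and snoRNA genes the ribosomal list had 16 of 75 (exact adjusted p = 2.5e-17). The 226 genes include mitochondrial ones, and 214 genes had a nuclear summit. Only 150 nuclear summits lay in these windows, since neighbouring genes can share a summit. Examples are rps-3A with ifet-1, and hsp-60 with Y22D7AL.10. A summit at a named gene may therefore belong to a neighbour, and the tests treat genes as independent. Oxidative phosphorylation genes (5 of 43, exact adjusted p = 0.0011) were represented by cox-6B (33.1), atp-1 (27.7), cox-5B (23.4) and cox-6A (22.8), nuclear genes of mitochondrial respiratory and ATP synthase subunits, and by atp-3 (22.3). That list did not pass with the strongest regions of replicate 3 alone (2 genes, exact adjusted p = 0.27) or with the stronger regions of the list (2 genes, exact adjusted p = 0.16). The region at cox-6A was also within 500 bp of a tRNA, snRNA or snoRNA gene. Away from such genes oxidative phosphorylation had 4 of 43 genes (exact adjusted p = 0.0027). The list of heat shock proteins and chaperonins (5 of 62, exact adjusted p = 0.0046) was represented by cct-8 (36.4), cct-5 (23.6) and cct-7 (23.2), subunits of the cytosolic chaperonin, by the mitochondrial chaperonin gene hsp-60 (27.5), and by hsp-1 (22.2). Its call was lost with the stronger regions of the list (1 gene, exact adjusted p = 0.99) and among genes with a pooled relaxed region (exact adjusted p = 0.093). Chemosensory receptor genes had a summit less often than other genes, with 2 of 1307 (exact adjusted p = 0.00082), srh-269 (36.2) and sre-23 (26.8). Both of those regions were also within 500 bp of a tRNA, snRNA or snoRNA gene. Against circular shifts of the summits, which keep gene clusters together, the 3 enriched lists passed (adjusted permutation p = 0.00135) and the chemosensory list did not (adjusted permutation p = 1). These shifts do not keep the overall enrichment at 5′ ends. They gave means of 0.299 ribosomal and 3.59 chemosensory genes, against 0.848 and 14.8 from the overall share. The shifts therefore do not compare a list with other genes, and they make an enriched list pass more easily and a depleted one less easily. The chemosensory list did not pass among genes with a pooled relaxed region (exact adjusted p = 0.25) or with the stronger regions of the list (exact adjusted p = 0.10) either.

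The other lists did not pass the test. Chromatin and transcription machinery had 5 of 118 genes, set-16 (37.9), swsn-3 (34.5), mdt-26 (26.2), met-1 (24.9) and hda-6 (22.4), with an exact adjusted p of 0.060. That list passed with nuclear regions only (exact adjusted p = 0.048) and against circular shifts (adjusted permutation p = 0.00135). It also passed with a window of 500 bp upstream to 200 bp downstream (exact adjusted p = 0.021) and away from short genes (exact adjusted p = 0.015). In 5 of 9 alternatives it did not pass. The circular shifts gave a mean of 0.465 genes of that list, against 1.33 from the overall share. The pass against them therefore does not compare the list with other genes. Core and linker histones had 3 of 83, htz-1 (30.3) and the pair his-67 and his-68, which share a region (27.7), and germline and oocyte genes had 2 of 51, glh-2 (24.8) and mex-1 (24.4). Single genes were found for translation factors (eef-1A.1, 29.5), the vacuolar ATPase (vha-1, 26.95), Sm and SR proteins (snr-4, 34.8), cell cycle and replication (pcn-1, 23.1), cuticle collagens (col-63, 31.6), neuropeptides (ins-39, 27.8) and C-type lectins (clec-126, 41.8). Enzymes of the cytochrome P450 and phase II families had 2 of 185 genes, gst-27 (26.3) and cyp-43A1 (22.4). The regions at snr-4, clec-126, gst-27 and cyp-43A1 were also within 500 bp of a tRNA, snRNA or snoRNA gene. They may therefore belong to those genes and not to the protein-coding ones. The genes atp-3, hsp-1, his-68, mdt-26, met-1 and hda-6 were named after their values were seen, to complete their short lists. No thresholded summit was found at the 5′ end of F-box genes (0 of 322), nuclear hormone receptors (0 of 274), homeobox genes (0 of 92), major sperm proteins (0 of 54), muscle genes (0 of 39), proteasome subunits (0 of 33), pan-neuronal genes (0 of 31), intestinal genes (0 of 31), T-box genes (0 of 22), stress signalling and ubiquitin genes (0 of 18) or vitellogenins (0 of 6). At the overall share of 1.13%, these lists would have between 0.0679 and 3.64 genes each, so the absence of a summit was not separable from chance (exact adjusted p between 0.25 and 1).

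The genes of ASE asymmetry, the process LSY-27 is known for, had no thresholded region. None of the 26 protein-coding members of that list had a thresholded summit in the window, where 0.294 would be given by the overall share (exact Fisher adjusted p = 1). In the pooled relaxed list 7 of the 26 had a region there (26.9%), against 41.5% of all protein-coding genes (exact Fisher p = 0.16). The strongest was at unc-37, a Groucho corepressor gene, with a signal of 6.69 and rank 7203 of 30000, followed by the receptor guanylyl cyclase gene gcy-22 with 5.90. The nearest thresholded summit was 161 kb from lsy-6, the microRNA gene that acts in the left ASE neuron, and 601 kb from lsy-27 itself. Signal from a few neurons in whole animals could not be separated from other tissues here.

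Across chromosomes, regions were fewest relative to length on chromosome V, with 40 of 318 nuclear regions (12.6%) against 20.9% of the nuclear length (exact binomial adjusted p = 0.0011). The share on V did not pass the test with the strongest regions of replicate 2 (17.7%, exact adjusted p = 0.37) or with the stronger regions of the list (13.5%, exact adjusted p = 0.078). The X chromosome held 72 regions (22.6%, exact 95% interval 18.2 to 27.6) against 17.7% by length, which did not pass after adjustment (exact binomial p = 0.023, adjusted p = 0.068). Against the chromosome shares of the pooled relaxed list (exact adjusted p = 0.0072) and of protein-coding genes (exact adjusted p = 3.9e-05) the X share passed, as did the low share on V (exact adjusted p = 0.032 and 3.5e-07). The X share did not pass in the stronger regions (exact adjusted p = 0.078) or with the strongest regions of replicate 2 or 3 (exact adjusted p = 0.70 and 0.18). The X share differed between regions near short genes and the others (exact Fisher adjusted p = 3e-07). Near tRNA, snRNA and snoRNA genes it was 61 of 187 (32.6%, exact adjusted p = 4.2e-06, above the length share), and away from them it was 11 of 131 (8.40%, exact adjusted p = 0.0078, below it). The split is by closeness to these genes, so the X share near them depends on where the genes lie. Its difference from the other set is therefore not separate evidence about X. Of the nuclear tRNA genes, 276 of 612 (45.1%) are on X, and 28.3% of those had a summit, against 20.5% on the autosomes (exact Fisher p = 0.029, adjusted p = 0.17). Away from short genes, chromosome III held more regions than its length gives, 34 of 131 (25.95% against 13.7%, exact adjusted p = 0.0011). On the autosomes, 143 of 246 summits (58.1%) lay in the central 50% of the chromosome (exact binomial p = 0.013). That excess did not pass in the stronger regions alone (59.5%, exact binomial p = 0.057) or against the pooled relaxed list (exact binomial p = 0.20). It passed with the strongest regions of replicate 2 (56.9%, exact binomial p = 0.030) or replicate 3 (58.2%, exact binomial p = 0.011) and away from short genes (76 of 120, 63.3%, exact binomial p = 0.0045), and did not pass near them (67 of 126, 53.2%, exact binomial p = 0.53), but these 2 shares did not differ past the threshold (exact Fisher adjusted p = 0.12).

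**Figure D3:**
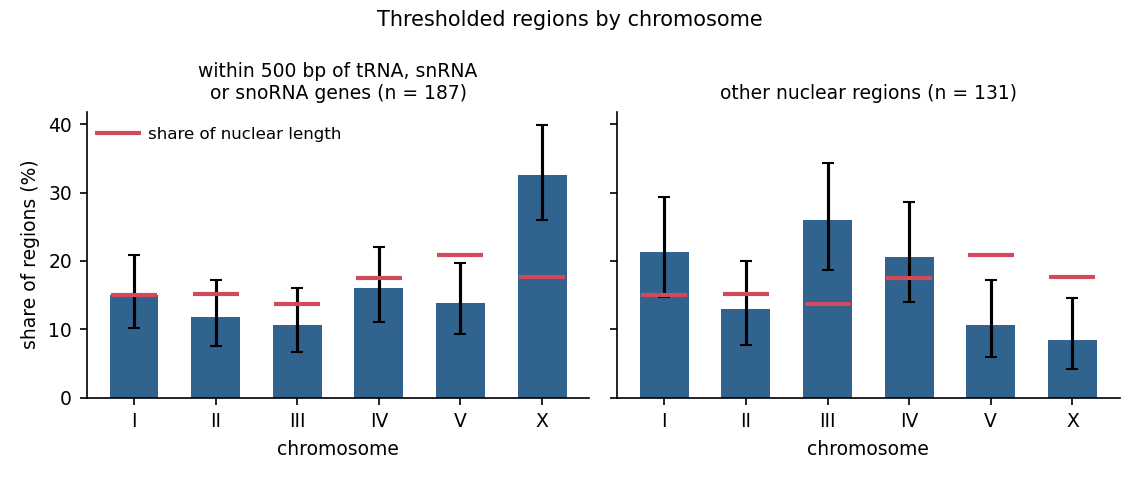
Share of thresholded regions (%) on each chromosome, with exact 95% intervals, for the 187 nuclear regions within 500 bp of tRNA, snRNA or snoRNA genes (left) and the other 131 (right). The red marks give each chromosome's share of the nuclear length; X holds 32.6% of the first set and 8.40% of the second.

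The sequences shared by the summits differed between the same sets of regions. The 6-mers most enriched within 50 bp of the 342 summits, compared with flanks 300 bp away, were CGAACC/GGTTCG (67 summits and 5 flanks, exact McNemar adjusted p = 1.2e-11), GAACCC/GGGTTC (57 and 3), GTTCGA/TCGAAC (77 and 16), GCGCGC (35 and 0) and CGCGCA/TGCGCG (34 and 1). The first 3 overlap within the sequence of the B box, the internal promoter element of tRNA genes. Away from tRNA, snRNA and snoRNA genes, CGAACC/GGTTCG no longer passed the test (3.05% of summits, exact adjusted p = 1), while GCGCGC was the most enriched 6-mer (24 of 131 summits and 0 flanks, exact adjusted p = 0.00025). CGAACC/GGTTCG was more frequent near short genes (33.7% of summits, exact Fisher adjusted p = 3e-12) and GCGCGC away from them (18.3% against 5.88%, exact Fisher adjusted p = 0.00099). The difference in CGAACC/GGTTCG follows largely from the split itself, since tRNA genes hold the B box. The most depleted 6-mers were CTGAAA/TTTCAG (15 summits and 68 flanks, exact adjusted p = 2.5e-07) and AAATTA/TAATTT (33 and 92). In all, 204 6-mers were enriched and 111 depleted among 2080 tested. Base composition differed along with them, since the GC content of nuclear summits was 48.5% ± 7.52 (SD, n = 318 regions) against 35.7% ± 6.45 in their flanks, higher at the summit in 284 regions.

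The replicates shared regions far more often than chance, while a shared order of strength was not found over the whole list. Of the 342 strongest regions of replicate 2, 118 (34.5%) overlapped one of the 342 strongest of replicate 3, against a mean of 16.4 after circular shifts (permutation p = 0.0002, the smallest that 10000 shifts can give). Of the thresholded regions, 330 of 342 (96.5%) overlapped a relaxed region in both replicates, with a median matched rank of 279 among 12414 in replicate 2 and 191.5 among 29326 in replicate 3. The thresholded list was made from these same lists, so this share is not independent evidence of agreement. All 342 were found in replicate 3, so those missing from a replicate lacked a region in replicate 2, where matched ranks reached 12180. Across those 330 regions, which are not independent replicates, Pearson's r of the signal values was 0.86 (permutation p = 1e-05, the smallest possible) and Spearman's rho 0.082 (permutation p = 0.14). The 2 correlations belong to 1 family, with adjusted permutation p = 2e-05 and 0.14. Without the 2 regions farthest from the median in replicate 2, r was 0.67. In the stronger regions alone rho was 0.21 (permutation p = 0.0062, n = 165 regions), and −0.15 without the mitochondrial ones among them (permutation p = 0.070, n = 145, a setting chosen after the data were seen). Both positive correlations that passed rested on the mitochondrial regions, since over the 309 nuclear regions r was 0.020 (permutation p = 0.72) and rho −0.11 (permutation p = 0.049, adjusted p = 0.098). The regions entered had been selected on both replicates by the thresholding, and all had a signal of at least 22.1 in the pooled data. Such a selection can by itself lower a correlation between replicates. A low value over the nuclear regions therefore does not show that the replicates order regions differently. The classes of genes near summits were found in each replicate alone, with tRNA genes near 28.1% of the strongest 342 summits of replicate 2 and 38.01% of those of replicate 3, and snoRNA genes near 13.5% and 14.04%. Random placement gave means of 4.54% and 5.54% near tRNA genes, and 0.346% and 0.352% near snoRNA genes. These strongest regions include 20 mitochondrial ones in replicate 2 and 25 in replicate 3.

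**Figure D4:**
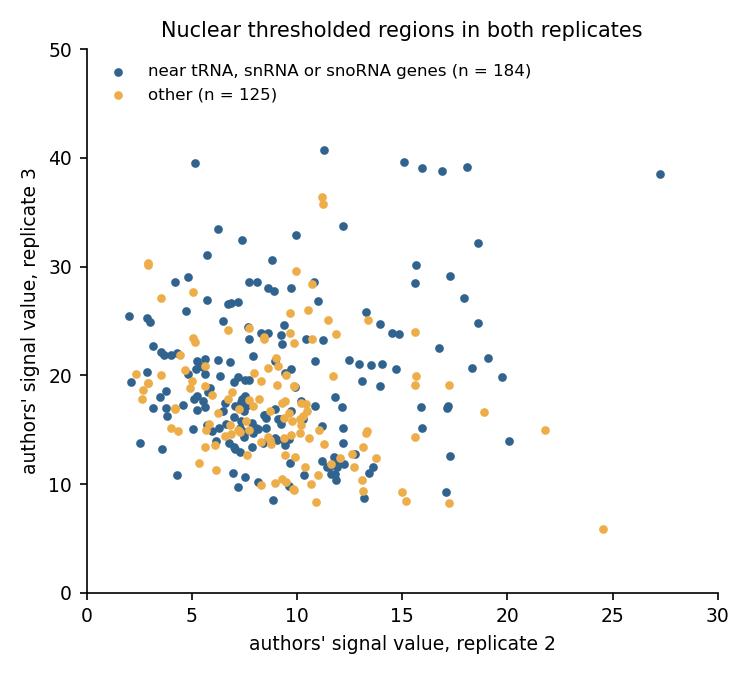
Authors' signal value of the matched region in replicate 2 (horizontal) and in replicate 3 (vertical) for the 309 nuclear thresholded regions found in both, coloured by whether a tRNA, snRNA or snoRNA gene lies within 500 bp. Pearson's r was 0.020.

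The submitters also gave lists for build ce10. The thresholded list held 330 regions there against 342 in ce11, with 24 mitochondrial regions in each. Per chromosome the largest difference was on chromosome I, with 52 regions in ce10 and 56 in ce11, and X held 71 and 72. No coordinates were converted between the builds.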

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

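The test of the mitochondrial regions below was chosen only after their number and signal values had been seen. The thresholded list held 24 mitochondrial regions, which were left out of the chromosome comparisons and stood out as data that no chromosome comparison used. They covered 42.9% of the mitochondrial genome of 13794 bp, while the nuclear regions covered 0.100% of the nuclear genome. Background from the many copies of the mitochondrial genome stays open as a possible explanation of the high signal values. The coverage does not decide it, since so many regions on so short a genome nearly fix that share. The control reads were not analysed here, and no biological explanation was tested.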

How the results depend on the processing

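The settings restricted to nuclear regions, to stronger nuclear regions, or to regions away from tRNA, snRNA and snoRNA genes, were chosen after seeing the data, and the others before. The enrichment at protein-coding 5′ ends (39.2% to 80.9%), the overlap of the strongest regions between replicates (30.7% to 37.4%) and the enrichment of tRNA, snoRNA and snRNA genes passed under the alternatives run for them, but the 187 regions near short genes taken alone did not pass for protein-coding 5′ ends (23.5%, permutation p = 0.36). The stricter threshold was the median signal of the list, so the number of regions it leaves is nearly fixed in advance. It left 171 regions, the stricter set of the results below, of which 165 were also found in both replicates. The share found in both replicates was 90.9% with 50% reciprocal overlap, 87.1% with summits within 100 bp and 35.4% with only the strongest regions of each replicate. Spearman's rho between replicates was 0.21 in the stronger regions and passed the test, and turned to −0.11 with nuclear regions only, where Pearson's r was 0.020; in the stronger nuclear regions they were −0.15 and −0.035. The X share of 22.6% passed against the pooled relaxed list and against the share of protein-coding genes, and fell to 8.40%, below the share by length, away from short genes. The share in the autosome centres did not pass in the stricter set (59.5%, with fewer regions) or against the pooled relaxed list (58.1%). Where 4 gene lists passed in the main setting, 1 passed in the stricter set and 2 against genes with a pooled relaxed region. Oxidative phosphorylation did not pass in the strongest regions of replicate 3 alone (2 genes, exact adjusted p = 0.27), and heat shock did not against genes with a relaxed region (exact adjusted p = 0.093); the stricter set ended the calls of both and of the chemosensory list. The count of enriched 6-mers, 204 in the main setting, was 71 in the stricter set, 413 against other relaxed summits and 25 away from short genes, with 9 enriched 8-mers; leaving out a replicate gave 120 to 185. The difference in signal between protein-coding 5′ ends and other regions, 0.479 in the main setting, was −0.475 in the stricter set, −0.833 with nuclear regions only and −0.474 to −0.330 without a replicate, with no setting past the threshold. Among classes that had not passed, ribosomal RNA genes were above the random share without replicate 2 (2.05%) and piwi-interacting RNA genes at 1000 bp (7.02%). Neither was past the threshold. Ribosomal RNA genes passed against other relaxed regions (1.46%, exact adjusted p = 2.8e-10). That call rests on mitochondrial DNA, since all 5 summits were mitochondrial while 29627 of the 29628 other regions were nuclear. Among nuclear regions 0 of 318 summits lay near such a gene. For single classes, lists, 6-mers and the chromosome V share, 106 alternatives kept the direction and the side of the threshold, 10 no longer passed, 6 newly passed and 3 turned. Apart from the mitochondrial ribosomal RNA genes and smaller region numbers in the stricter and restricted sets, the cause of these changes was not tested. Read depth, which limits how many regions can be found, was not given in the sources used here.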

Other observations

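The test of promoter occupancy and the test on the control reads below were chosen only after the results they measure had been seen, and the other tests were written before. Beyond the classes compared in the report, thresholded summits lay at other genes for small structural RNAs, picked out after their values were seen. Besides rpr-1, these were mrpr-1, the RNA of ribonuclease MRP (chromosome II, 7200132 to 7200447, signal 27.8, summit 57 bp inside the gene), and srpr-2.2, a signal recognition particle RNA gene (chromosome III, 5031349 to 5031664, signal 25.7). The microRNA genes were mir-5549, whose region on chromosome III is also the one at the 5′ end of eef-1A.1 (29.5), and mir-51 on chromosome IV (24.8).

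The regions at tRNA, snRNA and snoRNA genes, 58.8% of the nuclear regions, could have technical sources. GC content is not enough, since random places matched in chromosome and GC content lay near these genes in at most 4.40% of regions over 1000 draws. Reads shared between near-identical copies do not account for the snoRNA genes, since of the 306 with at least 90% of their 32-mers unique in the genome, 16.99% (exact 95% interval 13.0 to 21.7) had a summit. For tRNA genes that explanation stays open, because only 26 have such sequence and 1 of them, K02A4.t1, had a summit within 500 bp (3.85%, exact 95% interval 0.0973 to 19.6), which lies inside K02A4.t2, against 24.9% of the others (exact Fisher p = 0.0094). That test covers only sequence inside the genes. Over the whole of the 187 regions near tRNA, snRNA or snoRNA genes, the median share of unique 32-mers was 82.8%, against 100% in the other 131. This value was not split by class and does not decide the question for tRNA genes. General occupancy of strongly transcribed promoters was not decided either, since the ratio of the shares of ribosomal protein and tRNA genes (0.999) rests on shares already seen and unlike windows, and no other factor or untagged strain was analysed here.

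The gene lsy-27 lies in an interval of 58.2 kb on chromosome V (17319301 to 17377454) with no region in the pooled relaxed list, the sixth longest of 28435 such intervals, whose median was 1840 bp. Sequence that cannot be placed uniquely is unlikely to account for it, since 90.9% of its 32-mers occur once in the genome, against 91.4% genome-wide. Clusters of F-box and chemosensory receptor genes were not decided as an explanation, as 1.41% of those genes (exact 95% interval 0.897 to 2.11) lie in intervals as long, against 0.526% of all protein-coding genes. That share was below the one predicted beforehand for this explanation. Its interval reached past the limit set for calling the explanation unfit. Of the 105 protein-coding genes in such intervals, 23 were of these families. Extra copies of the tagged gene in the control reads could also lower the values there. The interval around lsy-27 was at or above the 99.3rd percentile in each replicate's list (46.6 kb in replicate 2 and 45.7 kb in replicate 3). In replicate 2 it ranked only 88 of 12227, and 5.45% of the nuclear genome lay in intervals as long. In replicate 3 it ranked 8 of 28506, with 0.631% in intervals as long, against 0.557% in the pooled list. This does not tell the control from the immunoprecipitate, and no biological explanation was tested.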
